A study of Mus musculus with 4 samples.

How the data were processed

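Poly-A RNA from cultured pancreatic fibroblasts of wild type and KPC mice (2 libraries each, called biological replicates in the labels) was sequenced as single reads, per the labels' protocols. The submitters' processing notes name FastQC 0.10.1, TopHat2 2.0.3, SAMtools 0.1.18 and bedtools (version not given in the sources used here) and the mm10/GRCm38 build, without saying which step used which. For each sample the authors deposited 1 table with no header, whose 38921 rows are the same gene intervals in the same order. Each row gives the position, the symbol, a read count, the number of bases covered, the interval length and the fraction of the interval covered. That the deposited count is a raw count of reads was read from the values: whole numbers with different totals per library. That it runs over the whole interval, introns included, was assumed from the deposited positions and interval lengths. The deposited fraction of bases covered and the deposited number of covered bases were used only to check the counts.

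Several properties of these counts limit what they can show. Rows with a count of 1 most often covered 37 bases (82.8% of them) and at most 41. Processed pseudogenes, by GENCODE M21 biotype, held 25.5%, 26.0%, 25.7% and 27.1% of the counts in wild type 1, wild type 2, KPC 1 and KPC 2, and 153 tested rows shared all 4 counts with another row, so reads with several matches were counted more than once. Totals are therefore sums over overlapping rows, not numbers of reads. No strand was apparent in the counts, so overlapping and antisense genes, paralogs and pseudogenes are uncertain. The 37 mitochondrial rows held 0 counts. Biotypes were taken from GENCODE M21 by position or symbol, which matched 97.3% of rows. Symbols on more than 1 row (353 rows) were tested row by row, and a gene list used the row with the most counts.

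The 4 count tables were analysed with edgeR 4.0.16 in R 4.3.3, with filterByExpr (minimum count 10), TMM factors, which lay between 0.988 and 1.02, and the two-sided quasi-likelihood test of KPC against wild type, adjusted by Benjamini-Hochberg over 23046 rows at 0.05. The common dispersion was 0.103, and 2 residual degrees of freedom and 2.76 prior degrees of freedom set the spread. Standard errors are the unshrunk log2 fold change divided by the square root of the F statistic. An exact permutation test of 2 libraries against 2 has 6 arrangements and was not used, since it cannot reach 0.05. Between the libraries of a group, the chi-square of counts per degree of freedom was 147 in wild type and 80.9 in KPC, so no library repeated another.

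Before the data were examined, 41 gene lists with 718 entries were fixed for fibroblast states, signalling, metabolism, position, other cell types and technical checks. 717 entries had a row and 653 were tested. The 38 lists with at least 5 tested genes were tested two-sided with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 38. Lists share some genes, such as Krt19 and Ngfr. The naming rule, also fixed then, took up to 12 genes in each direction with a mean of at least 5 CPM and no overlap between groups, those past the threshold first and then by smallest p, up to 4 genes of smallest p per list, 11 genes chosen beforehand, and the 5 rows with the most counts in each group. Because 0 genes passed, all 24 genes of its first part were filled in by p. Some genes that the rule took are not reported here.

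Scripts were tested on 10 simulated sets with the real means and library sizes and a spread drawn at random around the fitted dispersion trend. Genes were drawn independently of each other. In each set 200 of 23046 genes changed by the folds below, and the members of the shifted lists below rose 2-fold besides. For KPC against wild type, edgeR recovered 0% of the genes changed 2-fold, 4-fold and 8-fold and made 0 false calls. DESeq2 1.42.0 recovered 5.37%, 44.0% and 76.1% of them and called 224 unchanged genes on average in sets with no change. Camera called 100% of 100 simulated lists of independent genes shifted 2-fold and 0.667% of 300 unshifted lists. The unshifted lists held independent genes too, so neither rate covers lists whose genes vary together. Among the lists called below, the estimated correlation between genes ran from 0.11 (p53 targets) to 0.99 (endocrine markers).

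Alternatives were edgeR with RLE, upper quartile or no composition factors, other count filters, a test against a 1.5-fold change, thresholds of 0.01 and 0.10, DESeq2, limma voom, a replicate block, and each library left out, with the lone library of its group assumed to vary like the other group. For the lists, camera with an estimated correlation, fry and voom values were tried. Intervals of single-library values are exact Poisson intervals at 95%, and with the 3-count floor they cover counting error only. Figures were drawn with matplotlib 3.10.9.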

Results

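RNA from cultured mouse pancreatic fibroblasts was sequenced in 4 libraries, 2 from wild type animals and 2 from KPC animals. KPC is the usual name of a mouse model of pancreatic cancer in which engineered alleles, a mutant Trp53 allele among them, are switched on by Cre in Pdx1-expressing cells; the labels give the name alone. The comparison asked how fibroblasts of the KPC pancreas differ in gene expression from those of the wild type pancreas. The deposited tables hold a read count for each of 38921 gene intervals. Counts summed to 53232634 in wild type replicate 1, 22302141 in wild type replicate 2, 57926327 in KPC replicate 1 and 68312367 in KPC replicate 2. After filtering, 23046 rows were tested, and levels are given as CPM after TMM scaling.

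Among the genes engineered in the model, Trp53 (chromosome 11, 69580359 to 69591873 in the mm10 build) stood at 34.2 and 29.1 CPM in the wild type libraries and at 22.8 and 16.7 CPM in the KPC libraries. Its log2 fold change was -0.68 ± 0.23 (SE), and it did not pass the edgeR quasi-likelihood test (adjusted p = 0.541). These counts are taken to cover whole gene intervals and do not tell a mutant allele from a normal one. Pdx1, a pancreatic epithelial and beta cell transcription factor, had 0, 3 and 4 counts in wild type 1, wild type 2 and KPC 1 and 177 counts in KPC 2, and was too low to be tested. That is 2.61 CPM in KPC 2, with an exact 95% Poisson interval of 2.24 to 3.02, and the 0 in wild type 1 allows up to 0.0571 CPM (3 counts).

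The genes of smallest p with no overlap between groups included Wfdc2, Lgals3 and Wnt4 on the higher side in KPC and Nupr1 on the lower side. Wfdc2, a secreted protein of epithelia, averaged 0.834 ± 0.0224 CPM in wild type and 80.9 ± 44.8 CPM in KPC (SD, n = 2 each), and the galectin gene Lgals3 averaged 41.9 ± 6.34 and 244 ± 39.2 CPM. Wnt4, which encodes a Wnt ligand, averaged 5.76 ± 0.584 and 24.6 ± 0.591 CPM, a log2 fold change of 2.09 ± 0.19 (SE). The tight junction gene Cldn18, the adaptor gene Dok2, the leukocyte genes Cd53 and Srgn, the inflammasome adaptor gene Pycard, and Gda, Tns4, Stac2 and Hal were the other 9 genes that the naming rule took as higher, with log2 fold changes from 1.80 (Srgn) to 5.10 (Hal). In the other direction, Nupr1, a stress-responsive regulator, averaged 156 ± 13.8 CPM in wild type and 54.1 ± 1.06 CPM in KPC. The protease genes Tll1 and Prss23, the transcription factor genes Gata2, Foxs1 and Zfp949, the death receptor gene Fas, and Psrc1, Brinp1, Rasgrp3 and the U1 small nuclear RNA copy Rnu1a1 were also taken as lower, with log2 fold changes from -1.32 (Foxs1) to -4.63 (Rnu1a1).

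None of the 24 genes taken by the rule passed the edgeR test, which recovered 0% of simulated 8-fold changes. edgeR's quasi-likelihood test called 0 genes higher and 0 genes lower at an adjusted p of 0.05, and its smallest adjusted p was 0.211. At an unadjusted p under 0.05 there were 1090 rows higher and 909 lower, where 1152 in all would be expected by chance; with upper quartile factors there were 917 higher and 1087 lower. limma voom called 0 genes, and DESeq2 called 333 genes higher and 294 lower. The 24 genes were among them, with a DESeq2 adjusted p from 1.86e-34 (Wfdc2) to 0.000355 (Fas). In simulated sets with no change DESeq2 called 224 genes on average. Without wild type replicate 2, edgeR called 429 higher and 406 lower, and without wild type replicate 1 it called 0 and 5. Here and below, leaving out a library leaves 1 group with a single library, which the fit assumes to vary like the other group. The groups did not overlap in 41.1% of tested rows, where 2 libraries against 2 give 33.3% by chance. The labels call the libraries biological replicates and give no animals or cultures, so the p-values measure the spread between these libraries. On log2 CPM, wild type 2 correlated at 0.949 with wild type 1 and at 0.958 and 0.969 with KPC 1 and KPC 2. Wild type 1 correlated at 0.9295 and 0.931 with KPC 1 and KPC 2, which correlated at 0.978 with each other. By this measure wild type 2 was closer to the KPC libraries than to wild type 1.

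Markers of macrophages were higher in the KPC libraries, and epithelial markers overlapped more. All 17 macrophage and myeloid markers had a positive log2 fold change in KPC, with a median of 3.03, and the list rose by limma camera (adjusted p = 1.31e-11). At the level of genes, 15 of the 17 had an unadjusted edgeR p under 0.05, 0 passed over all genes and 7 passed adjusted over the list alone. The mannose receptor gene Mrc1 stood at 1.67 and 4.43 CPM in wild type and 31.5 and 26.4 CPM in KPC, Cd68 at 1.08 and 5.23 against 18.8 and 28.9 CPM, and the pan-leukocyte gene Ptprc at 0.875 and 1.21 against 3.89 and 7.65 CPM. The epithelial and ductal list rose by camera (median 1.81, 16 of 17 members positive, adjusted p = 0.000123); 5 of the 17 were higher in both KPC libraries than in both wild type libraries and 0 lower in both, where 20.6% of all tested rows were higher and chance gives 16.7%. Muc1 stood at 0.247 and 2.24 CPM in wild type and 17.7 and 9.27 CPM in KPC, and the keratin gene Krt19 at 5.23 and 20.1 against 64.7 and 34.9 CPM. Epcam did not separate the groups, at 0.190 and 13.6 against 5.41 and 18.1 CPM. Of the epithelial members, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. The epithelial call ended without wild type replicate 1 (median 0.715, adjusted p = 0.159), and the median was 5.64 without wild type replicate 2 (adjusted p = 9.46e-10). With an estimated correlation between genes, all 11 lists called here and below lost their call, at an adjusted p of 0.715 for the macrophage, epithelial, endothelial, endocrine and Schwann lists.

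The endothelial, endocrine and Schwann cell lists were called lower in KPC by camera, but much of each difference lay in 1 wild type library. This was wild type 1 for the endothelial and Schwann lists and wild type 2 for the endocrine list. The endothelial list fell (median -2.77, adjusted p = 6.28e-05 by camera), with 8 of 14 members at an unadjusted p under 0.05 and 0 passing adjusted over the list alone. Emcn was at 248 CPM in wild type 1 (exact 95% Poisson interval 243 to 252) against 4.20 CPM in wild type 2, 1.04 in KPC 1 and 2.21 in KPC 2. Plvap was at 188 CPM in wild type 1 and at most 8.01 CPM elsewhere. Without wild type replicate 1 the endothelial median was -0.63 (adjusted p = 0.0116). The endocrine list fell (median -7.88, adjusted p = 0.00102), with 8 of 8 tested members at an unadjusted p under 0.05 and 8 passing adjusted over the list alone. The insulin genes Ins1 and Ins2 were at 215 and 229 CPM in wild type 2 (intervals 209 to 221 and 223 to 236) and at most 0.495 CPM in the other 3 libraries. Without wild type replicate 2 the endocrine median was -1.11, on few counts in members such as Ins1 and Chgb. Ins1 had 14 counts in wild type 1 against 0 and 10 in KPC, and Chgb had 19 against 15 and 26. The Schwann and neural list fell (median -0.19, 4 of 11 members with an unadjusted p under 0.05 and 3 passing adjusted over the list alone, adjusted p = 0.0381), led by Ngfr, Foxd3 and Sox10, and its median was 0.08 without wild type replicate 1 (adjusted p = 0.616). The Schwann call also ended without KPC replicate 1 (0.217) and with a filter of at least 1 CPM in 2 libraries (0.368). Ngfr stood at 15.1 and 2.01 CPM in wild type and 0.119 and 0.0737 CPM in KPC.

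**Figure D1:**
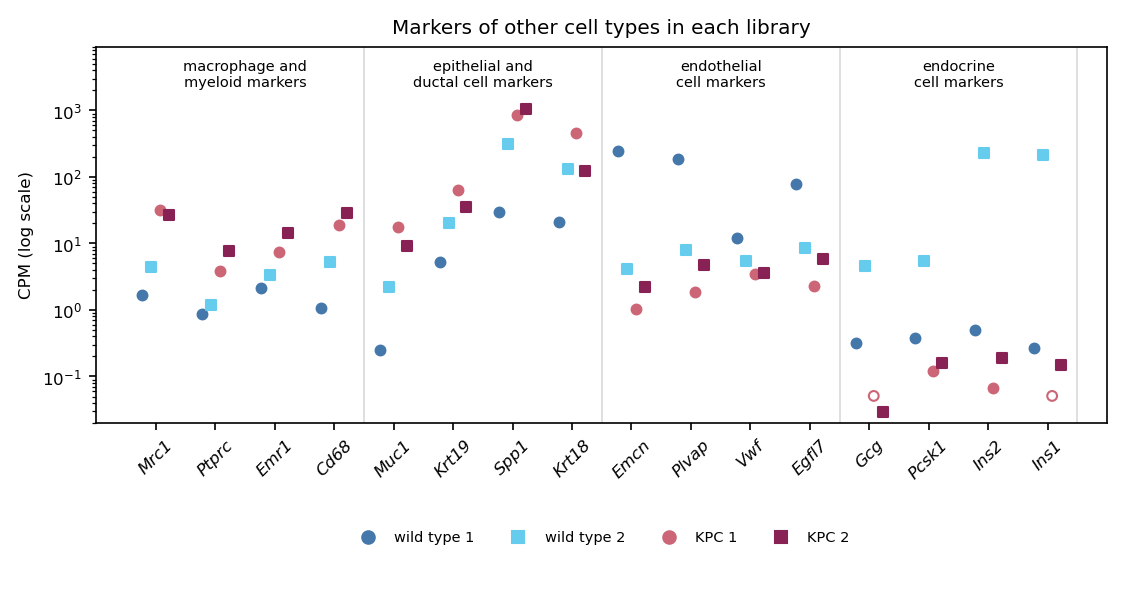
CPM on a log axis of the 4 genes with the smallest edgeR p in each of 4 marker lists, with 1 point per library (wild type blue, KPC red; circles replicate 1, squares replicate 2) and open symbols at the 3-count floor for a count of 0. Macrophage markers lie higher in both KPC libraries, Emcn reaches 248 CPM in wild type 1 alone, and Ins2 reaches 229 CPM in wild type 2 alone.

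The acinar list (median 0.17, adjusted p = 0.978), the pericyte and smooth muscle list (median 0.26, adjusted p = 0.479) and the adipocyte list (median -0.71, adjusted p = 0.0906) were not called by camera with all 4 libraries. The adipocyte list was called lower without wild type replicate 1 or KPC replicate 2 (adjusted p = 0.0224 and 0.0442). The leptin gene Lep, the adipocyte member with the smallest p, was at 1.62 and 1.97 CPM in wild type and 0.425 and 0.619 CPM in KPC. Its counts covered 197 and 119 of 13657 bases in wild type and 156 and 121 in KPC. They came from a short part of the interval and may not measure leptin expression. Of the lymphocyte markers, 3 were tested, too few for the list test. The interleukin 7 receptor gene Il7r, at 0.152 and 0.403 against 2.24 and 4.85 CPM, was the 1 that passed adjusted over the list alone.

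Target genes of the transcription factor p53 were lower in KPC. The list fell (median log2 fold change -0.58, camera adjusted p = 1.63e-05), with 24 of 28 members negative and 17 lower in both KPC libraries than in both wild type libraries, where 20.5% of all tested rows were and chance gives 16.7%. Psrc1 and Fas passed adjusted over the list alone, 0 members passed over all genes, and 10 had an unadjusted p under 0.05. Psrc1 stood at 22.3 and 19.6 CPM in wild type and 6.71 and 8.73 CPM in KPC, the cyclin gene Ccng1 at 198 and 174 against 114 and 114 CPM, and Mdm2, the ubiquitin ligase gene that p53 induces, at 57.1 and 49.9 against 33.1 and 34.3 CPM. Its adjusted p was 0.715 with an estimated correlation. The list kept its call without each library in turn, with medians from -0.66 to -0.40. The macrophage markers described above (median 3.03) differed between the same groups.

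**Figure D2:**
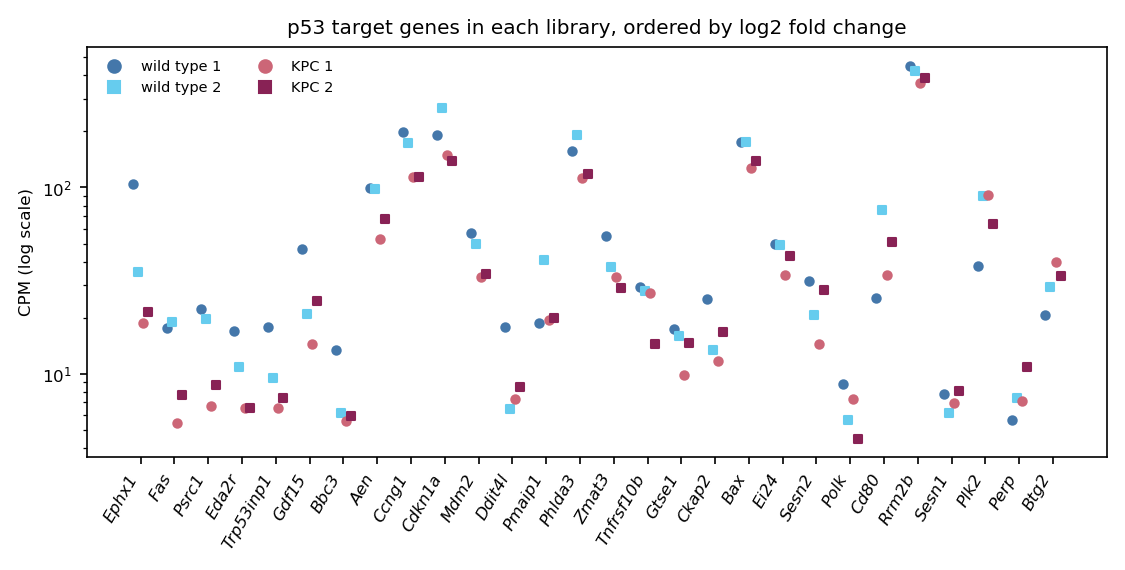
CPM on a log axis of the 28 tested p53 target genes, 1 point per library (wild type blue, KPC red; circles replicate 1, squares replicate 2), ordered from the lowest to the highest log2 fold change. In 17 genes both KPC points lie below both wild type points.

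Genes of cholesterol synthesis and of glycolysis were higher in KPC. The cholesterol biosynthesis list rose (median 0.73, 20 of 22 members positive, camera adjusted p = 1.63e-05), with 6 members at an unadjusted p under 0.05. The reductase gene Dhcr7 stood at 4.66 and 4.70 CPM in wild type and 13.3 and 8.51 CPM in KPC, and the squalene synthase gene Fdft1 at 39.9 and 34.2 against 82.1 and 52.7 CPM. The glycolysis and hypoxia list rose (median 0.54, 20 of 22 positive, adjusted p = 3.11e-05), with 5 members at an unadjusted p under 0.05. Pdk1, a kinase that restrains pyruvate oxidation, stood at 8.41 and 9.66 against 25.4 and 17.1 CPM, and the lactate dehydrogenase gene Ldha at 572 and 743 against 1043 and 961 CPM. In both lists 0 members passed over all genes or adjusted over the list alone, and the adjusted p was 0.715 with an estimated correlation. Without KPC replicate 1 the medians were 0.29 for cholesterol (adjusted p = 0.0299) and 0.36 for glycolysis (adjusted p = 0.00286), and without wild type replicate 1 the glycolysis median was 0.27 (adjusted p = 0.0339). Macrophage markers (median 3.03) were higher in the same libraries.

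3 weaker lists were called higher. MAPK feedback genes had a median of 0.35 (13 of 16 positive, 4 with an unadjusted p under 0.05, camera adjusted p = 0.0368). Spry2 stood at 16.9 and 19.5 against 33.7 and 33.4 CPM and the phosphatase gene Dusp6 at 13.8 and 15.4 against 32.8 and 23.4 CPM. Antigen-presenting and mesothelial markers had a median of 1.25 (9 of 12 positive, 4 higher and 1 lower with an unadjusted p under 0.05, adjusted p = 0.0368). Its members Cd74, the invariant chain gene, and Slpi stood at 0.361 and 1.65 against 10.5 and 3.89 CPM and at 1.41 and 15.2 against 57.0 and 88.5 CPM. Cav1, with 193 and 92.5 against 69.3 and 38.8 CPM, went the other way. Krt19 belongs to this list and to the epithelial one. Cell cycle genes had a median of 0.21 (23 of 28 positive, 2 with an unadjusted p under 0.05, adjusted p = 0.0494), with the replication helicase gene Mcm7 at 31.8 and 28.7 against 45.6 and 47.3 CPM. In these 3 lists 0 members passed adjusted over the list alone, and the adjusted p with an estimated correlation was 0.715 for MAPK feedback, 0.762 for antigen presentation and 0.849 for the cell cycle. The MAPK call ended without wild type replicate 1, wild type replicate 2 or KPC replicate 1 (medians 0.132, 0.46 and 0.00236, adjusted p = 0.127, 0.083 and 0.418). The antigen-presenting call ended without wild type replicate 1 or KPC replicate 1 (medians 0.686 and 0.981, adjusted p = 0.354 and 0.244), and its median was 3.25 without wild type replicate 2. The cell cycle call ended without wild type replicate 2 or KPC replicate 2 (adjusted p = 0.702 and 0.804, the latter with a median of -0.02) or with a filter of at least 1 CPM in 2 libraries (0.0527). Macrophage markers (median 3.03) were higher in the same KPC libraries, and Cd74 is also expressed by macrophages.

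**Figure D3:**
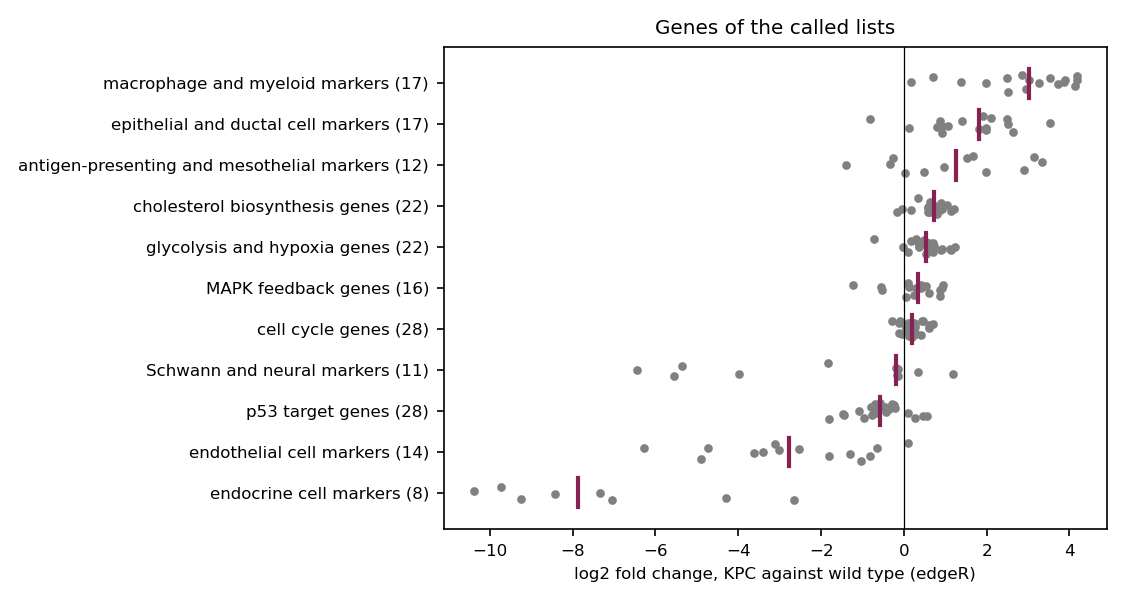
edgeR log2 fold change, KPC against wild type, of each tested gene in the 11 called lists (grey points, jittered vertically; number of genes in brackets), with each list's median as a red bar. Medians run from -7.88 for endocrine markers to 3.03 for macrophage markers.

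Apart from the antigen-presenting list, the lists of genes that define fibroblasts were not called with all 4 libraries. Col1a1 averaged 4402 ± 444 CPM in wild type and 5023 ± 313 CPM in KPC (SD, n = 2 each), Acta2, the smooth muscle actin of myofibroblasts, 4143 ± 1570 and 4161 ± 73.8 CPM, and Vim 2926 ± 1090 and 1714 ± 22.9 CPM. Pdgfra stood at 19.4 and 34.6 CPM in wild type and 13.8 and 48.7 CPM in KPC, and Pdgfrb at 194 and 132 CPM in wild type and 69.1 and 118 CPM in KPC. The adjusted p of these 5 genes was 0.579 or more in edgeR. Collagens (median -0.36, adjusted p = 0.105), other matrix proteins (-0.11, 0.758), matrix remodelling enzymes (0.05, 0.618), myofibroblast markers (0.08, 0.311), inflammatory fibroblast markers (0.11, 0.396) and fibroblast surface markers (-0.24, 0.311) were not called by camera. Of the members, 14 of 18 collagens and 16 of 23 other matrix proteins had a negative log2 fold change. Some calls appeared when 1 library was left out. Myofibroblast markers were called lower without wild type replicate 1 (median -0.361, adjusted p = 0.0475) and higher without wild type replicate 2 (0.577, 0.000129). Inflammatory markers (1.59, 0.000151) and matrix remodelling enzymes (0.261, 0.0238) were called higher without wild type replicate 2. Collagens were called lower without wild type replicate 2 or KPC replicate 2 (-0.607, 0.0435 and -0.596, 0.0495), other matrix proteins without wild type replicate 1 (-0.297, 0.0266) and surface markers without KPC replicate 2 (-0.891, 0.0161). Within the lists, values went both ways. Mmp2 stood at 67.4 and 134 against 268 and 317 CPM and Vcan at 31.1 and 41.4 against 63.5 and 77.0 CPM, while the collagen crosslinking enzyme gene Lox stood at 751 and 1177 against 356 and 508 CPM and Bgn at 1640 and 1439 against 567 and 889 CPM. Pancreatic stellate cell and quiescence markers had a median of -0.71 (adjusted p = 0.105), with 2 members passing adjusted over the list alone, Ngfr among them, and were called lower without KPC replicate 2 (-0.793, 0.0347).

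Among the signalling lists, Wnt pathway modulators (median 0.02, camera adjusted p = 0.226) held 2 members that passed adjusted over the list alone, Dkk3 at 12.8 and 20.8 against 58.1 and 77.4 CPM and the receptor gene Fzd1 at 7.88 and 13.4 against 32.0 and 33.0 CPM. In the growth factor list (median -0.15, adjusted p = 0.618, and a positive camera direction) Wnt4 alone did so. The Hedgehog (-0.01, 0.927, also with a positive camera direction), TGF-beta (0.06, 0.497), YAP and serum response (0.21, 0.184) and interferon (0.07, 0.938) lists were not called with all 4 libraries. Without wild type replicate 2 the YAP and serum response list was called higher (median 0.577, adjusted p = 0.0102), and without wild type replicate 1 its median was -0.0705. Not called either were the lists for senescence (0.40, 0.544), endoplasmic reticulum stress (0.03, 0.758), heat shock (0.15, 0.105), antioxidant genes (-0.12, 0.311) and imprinted growth genes (-0.79, 0.112). For the positional lists the values were -0.22 and 0.0698 for HOX A and B, -0.46 and 0.808 for HOX C and D, where the camera direction was positive, and -0.42 and 0.112 for pancreatic and splenic mesenchyme regulators. With a filter of at least 1 CPM in 2 libraries HOX A and B (adjusted p = 0.0246) and imprinted growth genes (0.0276) were called lower. Omissions gave further calls: HOX A and B lower without KPC replicate 1 (0.0183), HOX C and D higher (median 0.709, 0.0495) and mesenchyme regulators lower (median -0.636, 0.0495) without KPC replicate 2, and antioxidant (0.0401) and imprinted growth genes (0.00876) lower without wild type replicate 1. Among the mesenchyme regulators, the homeobox gene Nkx2-5, at 2.02 and 1.65 against 0.289 and 0.177 CPM, passed adjusted over the list alone.

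The technical lists were not called with all 4 libraries. Ribosomal protein genes had a median of -0.08 (camera adjusted p = 0.391), replication-dependent histone genes -0.25 (0.105) with Hist1h2ac passing adjusted over the list alone, and chromosome Y and X inactivation genes -0.29 (0.725). Histone genes were called lower without wild type replicate 1 (median -0.411, adjusted p = 0.0142) or KPC replicate 1 (-0.508, 0.0183), and ribosomal protein genes without KPC replicate 2 (-0.23, 0.0234). Mitochondrially encoded genes had 0 counts in every library and were not tested. The rows with the most counts included Col1a1, Acta2 and Gm20388 in both groups, Eef1a1 in KPC and Gm26924 in wild type. Gm26924 was at 10950 CPM in wild type 1 and between 1309 and 1913 CPM in the other 3 libraries, and Gm20388 is a long interval on chromosome 8 that spans other genes and shares their reads.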

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

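The alternatives with protein coding rows only and with identical rows collapsed were chosen after the data were seen. Counts of genes higher and lower in KPC were 0 and 0 in edgeR, and stayed 0 with RLE, upper quartile or no composition factors, both other filters, the 1.5-fold test, thresholds of 0.01 and 0.10, limma voom and the 2 added alternatives. DESeq2 called 333 higher and 294 lower; in simulated sets with no change it called 224 genes on average. Leaving out 1 library leaves a group with a lone library, assumed to vary like the other group; this gave 0 to 429 genes higher and 0 to 406 lower, with the highest counts without wild type replicate 2 and 5 lower without wild type replicate 1; the cause was not tested.

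Camera called 7 lists higher and 4 lower. An estimated correlation and fry each called 0 and 0, with smallest adjusted p of 0.715 and 0.698. Leaving out 1 library gave 4 to 9 lists higher and 5 to 10 lower, with myofibroblast markers lower without wild type replicate 1 and higher without wild type replicate 2. The macrophage, p53, cholesterol, glycolysis and endothelial lists kept direction and call under each omission. The endocrine list did so as well, but without wild type replicate 2 members such as Ins1 and Chgb had few counts left (14 and 19 in wild type 1), so this does not show that the fall holds without that library. Over the omissions the cell cycle median ran from -0.0214 (without KPC replicate 2) to 0.38 and the Schwann median from -1.64 to 0.0839 (without wild type replicate 1). With at least 1 CPM in 2 libraries the cell cycle and Schwann calls ended (adjusted p = 0.0527 and 0.368), the endocrine list had too few genes to test, and HOX A and B (0.0246) and imprinted growth genes (0.0276) were called lower. Voom values added HOX A and B (0.0486, lower) and heat shock (0.05, higher). With the replicate number as a block, 0 genes were called in either direction, and 4 lists were higher and 3 lower, since the MAPK, antigen-presenting, cell cycle and Schwann calls ended (0.0612, 0.0754, 0.0754 and 0.0612). The labels tie the libraries by a number alone, which also matched the level of Xist, so the block cannot be told apart from a term for it. Differences between replicates 1 and 2 in wild type and KPC correlated at 0.136 across genes, with 2 pairs.

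Of 75 named genes tested, 66 kept their direction under every alternative that tested them. Acta2 turned to -0.0578 with upper quartile factors and to -0.00450 with at least 1 CPM in 2 libraries, and Eif2s3y to 0.184 with limma voom. Over the omissions, Acta2 ran from -0.33 to 0.46, Pdgfra from -0.97 to 0.86, Epcam from -0.34 to 5.94, Eef1a1 from -0.36 to 0.12, Rpph1 from -1.83 to 1.60, Xist from -8.815 to 7.74, Eif2s3y from -5.711 to 4.725, Ddx3y from -0.461 to 0.236 and Uty from -0.832 to 0.23. The first 6 reversed without wild type replicate 1, the last 3 without wild type replicate 2, Acta2, Pdgfra and Epcam also without KPC replicate 2, and Rpph1, Eif2s3y and Uty also without KPC replicate 1. In no case had the gene passed the test, and the cause was not tested. Depth ranged from 22302141 to 68312367 counts and the 3-count floor from 0.0442 to 0.134 CPM. In edgeR, 2 libraries a group recovered 0% of simulated 8-fold changes, so its 0 calls do not bound the changes.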

Other observations

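The tests of dilution, of single libraries, of the fibroblast share and of small RNAs were chosen after the results were seen; the random lists, the leukocyte genes and the splits were fixed before their results. Classes of small noncoding RNA, looked at after their values were seen and with no list test, held rows with lower levels in KPC, of which 0 passed over all genes. All 59 tested ribosomal RNA rows, mostly named as 5S copies, were lower at an unadjusted edgeR p under 0.05. Their median log2 fold change was -3.43 (quartiles -3.57 and -3.28). Over all ribosomal RNA rows, tested or not and without TMM factors, the summed share was 222 and 119 CPM in wild type against 15.3 and 17.2 in KPC. Rows of such copies can count the same reads, so they are not 59 separate observations, and the same may hold for the small nuclear RNA rows. Of 100 small nuclear RNA rows 46 were lower and 2 higher. Of 47 miscellaneous RNA rows (median -1.25) 21 were lower and 0 higher. Small nucleolar RNAs had a median of -0.13, with 6 of 87 lower and 1 higher. MicroRNAs had a median of -0.09, with 8 of 151 lower and 0 higher. All microRNA rows, tested or not and without TMM factors, summed to 6590 and 5020 CPM in wild type against 3860 and 4480 in KPC. Reads of overlapping genes can count in these rows, so the values may not measure microRNAs. No test compared the classes. Xist, chosen after its values were seen, was at 136 and 58.4 CPM in replicate 1 of wild type and KPC and at 0.134 and 0.147 CPM in replicate 2. The Y genes Eif2s3y (0.266 and 0.238 against 24.96 and 13.9 CPM) and Kdm5d (0.552 and 0.646 against 3.13 and 2.34 CPM) went the opposite way. The Y genes Ddx3y and Uty were counted in all 4 libraries. Ddx3y was at 42.3 and 47.1 against 68.6 and 52.4 CPM, and Uty at 3.63 and 2.94 against 6.84 and 5.56 CPM. The Ddx3y counts covered only 715 and 735 bases in replicate 1 against 4293 and 5149 in replicate 2. The Uty counts covered 3127 and 2676 against 3338 and 6606 bases. Xist, Eif2s3y and Kdm5d thus separated replicate 1 from replicate 2 in both groups. The labels do not give the sex, and the Uty counts in replicate 1 left it unsettled.

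The p53 target list had a median log2 fold change of -0.58 in KPC. A single deciding library was argued against by the weakest median over the 4 omissions, -0.40, where the lone library left in 1 group was assumed to vary like the other group, and bias from expression level or interval length by 10000 random lists matched on both, whose central 95% began at -0.10. Dilution of fibroblast RNA by other cells cannot be told apart from a change in the fibroblasts: the 55 matrix and myofibroblast genes had a median of -0.13 and a lower quartile of -0.49, above the p53 median, but under each of the 4 omissions their lower quartile lay below it. Without wild type replicate 1 the median of these matrix and myofibroblast genes was -0.299 against -0.395 for the p53 list. It was 0.242 against -0.568 without wild type replicate 2. Without KPC replicate 1 it was -0.055 against -0.543, and without KPC replicate 2 it was -0.224 against -0.659. Trp53 itself was at -0.68 ± 0.23 (SE) without passing the test. The genotype, which the design names, stays open and untested, as do differences between cultures, which these 4 libraries cannot separate from it.

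Markers of other cell types differed between libraries. Myeloid cells among the cells of the KPC libraries are a candidate source: 27 other leukocyte genes, none in the fixed lists, had a median log2 fold change of 2.52, and 25 of them (92.6%) were higher in both KPC libraries than in both wild type libraries. In the fixed macrophage list the most abundant gene in KPC, Lyz2, reached 630 and 1416 CPM in KPC against 6.24 and 132 CPM. A lower share of fibroblasts in KPC would by itself raise the markers of every other cell type. The upper quartile of the endothelial markers was -1.10 while the lower quartile of the macrophage markers was 2.49. Over the omissions they were at most -0.272 and at least 1.52. These values speak only against that share as the whole cause. The endothelial fall was already known when the test was chosen, and Plvap was at 188 CPM in wild type 1 and at most 8.01 CPM elsewhere. The fibroblast share itself therefore stays open. Whether the marker differences came from the tissue or from the gravity separation of the cultures was not tested.

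For the ribosomal and small nuclear RNA rows, 2 explanations were tested, and neither test separates its explanation from a difference between genotypes. The first was many gene copies counting the same reads. Under it, the single-copy genes Rn7sk, Rmrp and Rpph1 were predicted not to share the direction. They were at -1.93 ± 0.40, -3.66 ± 1.14 and -0.63 ± 1.08 (SE), the last within its error of 0. Copies that share reads multiply rows in all 4 libraries alike, so the direction of single-copy genes cannot decide this. If more total RNA had passed the poly-A selection in wild type, the row over 18S ribosomal RNA, Gm26924, would be higher there; it was at 10950 CPM in wild type 1 but at 1788 CPM in wild type 2, against 1309 and 1913 CPM in KPC.

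For the 1999 rows at an unadjusted p under 0.05 in edgeR, the 3 splits of the 4 libraries into 2 and 2 are too few for a share under 0.05. The real split was the 1 split with that many, and the highest of the others gave 889.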
